A study of Mus musculus with 32 samples.

How the data were processed

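The libraries measured polyadenylated RNA from mouse liver. Per the labels' protocols, total RNA was extracted with Trizol and columns, only samples with an RNA integrity number above 6.5 were kept, messenger RNA was captured on poly-T beads, and non-directional libraries were sequenced as paired-end reads on an Illumina platform with 40 M reads planned per sample. Because such libraries do not mark strand, reads of antisense genes cannot be told apart where the genes overlap. The deposited table holds raw read counts per gene in 32 sample columns, and per the submitters' processing notes the authors used HISAT2, featureCounts and DESeq2 with the mouse genome build GRCm38 (mm10). Versions, the counting options for reads shared between copies of a gene, and any filter before the deposit are not given in the sources used here. The counts were whole numbers with a different total in each library, and were used as deposited. The table listed 54532 genes, of which 54409 identifiers (99.8%) were in the GENCODE M21 annotation of GRCm38, 53815 of them with the same symbol, and coordinates are from that annotation.

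Samples were grouped by diet and collection time as their titles give them, with sex as a further label, and each table column was matched to a sample by its name. The labels speak of mice but do not state that each replicate number is a different animal, so p-values measure the spread between these samples. No labels give a sequencing batch, a collection date or a light schedule. Replicates of a group were compared with a chi-square test of their counts over genes, and all 48 pairs differed by more than sampling noise (chi-square per degree of freedom from 20.7 to 357). Xist and the Y-linked genes Ddx3y and Eif2s3y were checked against the sex of each label. Total counts per library had a median of 37.2 M. Genes under 1 CPM in a group rest on few counts per library, and their values carry counting error as well as the spread between livers.

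Gene counts were analysed in R 4.3.3 with edgeR 4.0.16 by its quasi-likelihood test (robust estimates of dispersion), on libraries scaled by TMM, which sets 1 factor per library on the premise that most genes do not change. Genes with too few counts were removed by edgeR's default expression filter on the 8 groups, which left 17853. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. All 32 libraries entered 3 models, so that they share an estimate of the spread. The first had a term for each group plus sex, and gave the diet effect averaged over the 4 times, at each time, and the 3 df test that it is equal at all of them. The second had sex, diet and a cosine and sine of a 24 h period within each diet, and gave the rhythm in each diet (2 df), the difference between them (2 df) and the joint test of rhythm in either diet (4 df). The third had a term for each group plus sex within each diet, and gave the female minus male difference in chow, in cdHFD and its change. With collections 6 h apart the period cannot be estimated, a 12 h component is not separable from it except as a single contrast, and rhythm here means a difference between times of that shape.

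Log2 fold changes are edgeR's, moderated with a prior count of 2, while the SE beside each is the residual SE of the same contrast in a linear model of log2 CPM, which is a different estimator. Amplitude and peak time with their SE come from the same linear cosinor. CPM values are scaled by TMM, except those of Xist and Ddx3y in the check of sex labels, which are scaled by total counts, and mean and SD are over libraries. Fitted log2 values of genes with 0 to 3 counts in a group depend on the prior count. Among printed values this holds for Sult3a1 in cdHFD females, Kdm5d in females, Sult2a1 in chow males, and for Sprr1a, Vsig8 and Cftr in chow at 1 collection time each. Genes with slightly more counts in a group keep part of that dependence. Among them are Cyp3a44 and Cyp3a41b in chow males (0.0184 and 0.0179 CPM) and Ddx3y in chow females (0.0238 CPM).

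Models, gene lists, the rule for named genes and the alternatives marked as planned were fixed before the data were examined. The 42 gene lists hold pathways, cell types, other tissues and RNA quality markers and were written from textbook knowledge. For each, members past the threshold were counted over all genes tested and adjusted over the list alone. Camera from limma 3.58.1 tested whether a list shifted relative to other genes, with a preset correlation between genes of 0.01 and, as an alternative, with the correlation estimated from the data, adjusted over the 42 lists. Of the 30 lists that camera called under diet with the preset correlation, 14 higher and 16 lower, 3 held with an estimated correlation. These were chemokines, hepatocyte identity genes and p53 targets. Camera was also run under total counts alone, which was chosen after the data were seen. The share of list members among called genes was compared with that of all tested genes by Fisher's exact test, which was not among the tests fixed in advance.

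Genes ranked by size have a plain symbol and a mean of at least 5 CPM in the group where they are higher, while list members are named without that minimum, some of them under 1 CPM. For the averaged diet effect they are the 10 largest increases and 10 largest decreases with the same sign at the 4 times, and for each time the 3 largest in each direction among genes past the diet by time test. For rhythms they are the 10 largest amplitudes in chow, the 10 largest falls and 10 largest rises in amplitude among genes past the test of the difference, and the 5 largest shifts in peak among genes past both rhythm tests and the test of the difference. For sex they are the 6 largest in each direction in chow and the 8 largest changes in each direction with diet. From each list the rule takes the first 3 members whatever their result and the 3 called members of largest change, and from the clock list all members, and the text draws its examples from these. Some genes that the rule takes are not reported here, though they stay in every test and count.

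The clock reading of a library is the time of day at which the chow cosinor curves of 20 clock genes best match its log2 CPM, with the library itself left out of the curves. Its lead over the collection time was compared between diets, and library measures between diets, by two-sided permutation tests with 100000 resamples. This reading and the 12 h contrast were added after the data were seen.

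The tests named in this paragraph were tried on simulated counts drawn from the means and library sizes of the real libraries, with known changes in sets of 100 genes. The sex effect in chow and the diet effect at ZT2, ZT14 and ZT20 were not simulated. Between 17354 and 17418 simulated genes passed the filter in these runs, 17393 of them for the averaged diet effect. For the averaged diet effect 76 of 100 genes with a log2 change of 0.5 and 100 of 100 with a change of 1 were called, with 7 false among 183 calls. At ZT8 alone 8 and 78 were called, for rhythm in chow 68 and 99, for rhythm in cdHFD 66 and 99, for the difference in rhythm 27 and 95, and for sex in cdHFD 32 and 96. For changes of 1 and 2, 40 and 93 were called by the diet by time test and 73 and 98 by the sex by diet test. False calls were 8 of 94 at ZT8, 11 of 178 for rhythm in chow, 13 of 178 for rhythm in cdHFD and 7 of 129 for the difference in rhythm. They were 9 of 142 for diet by time, 2 of 130 for sex in cdHFD and 5 of 176 for sex by diet. The share of false calls lay above the adjusted p threshold at ZT8, for rhythm in each diet, its difference and diet by time. With equal amplitudes and equal spread simulated in both diets 50.9% of the 2046 called genes had the smaller amplitude in cdHFD. The real residual SD was larger in chow (0.377 against 0.311), and this was not simulated. The simulated share therefore does not show what equal amplitudes would give in the real libraries.

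Alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, DESeq2's size factors or total counts alone in place of TMM, no filter, no sex term, the replicate number as a block, any difference between the 4 times in place of a 24 h rhythm, genes past the rhythm averaged over both diets in place of the joint test, leaving out each library in turn and, chosen after the data were seen, leaving out replicates 3 and 4 of cdHFD at ZT2 and total counts alone for the gene lists. For each count, splits of the libraries into groups of the same sizes were compared, 100 of them, or all 35 for a single time, the real one included. No sample was left out of the main results.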

Results

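The series, whose title asks whether daily liver rhythms are disturbed in non-alcoholic steatohepatitis, compared the livers of wild-type mice fed for 2 weeks on chow or on a high-fat diet that lacks choline and is low in methionine (cdHFD). Choline is needed to make phosphatidylcholine, which the liver uses to coat the lipoproteins that carry triglyceride out of it. Livers were taken at zeitgeber time (ZT, hours after lights on) 2, 8, 14 and 20, which made 8 groups of 4 livers and 32 libraries of polyadenylated RNA. Each group held 2 males and 2 females except cdHFD at ZT14, with 3 males and 1 female, so that 17 libraries came from males and 15 from females. Total counts per library ran from 29.5 to 54.6 M (M for mega; median 37.2 M). They were 37.2 M ± 6.62 in chow and 38.7 M ± 6.001 in cdHFD (SD, n = 16 each; two-sided permutation p = 0.528). Xist, which is transcribed from the inactive X chromosome, lay at 267 CPM (counts scaled to library size, here by total counts) or more in every library labelled female and at 0.775 CPM or less in every library labelled male. The Y-linked gene Ddx3y lay at 13.3 CPM or more in the males and at 0.0976 CPM or less in the females.

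The makeup of the libraries differed between the diets before any single gene was tested. Alb, the gene of serum albumin, took 8.36% ± 1.55 of all counts in chow and 4.90% ± 0.454 in cdHFD, and the 10 most abundant genes took 23.2% ± 2.27 and 16.7% ± 1.17 (SD, n = 16 each). Mitochondrially encoded genes took 8.12% ± 2.36 of counts in chow and 5.12% ± 1.04 in cdHFD, and globin genes 0.0355% ± 0.0126 and 0.0219% ± 0.0107. Genes with at least 10 counts numbered 15336 ± 517 per chow library and 16555 ± 442 per cdHFD library, and the composition factor (TMM) that rescales each library was 0.821 ± 0.044 in chow and 1.22 ± 0.0822 in cdHFD. In two-sided permutation tests adjusted over 7 measures, p was 1.75e-05 for Alb, the top genes, the genes detected and the factor, 7e-05 for the mitochondrial share and 0.00253 for the globins. The unadjusted p behind the first of these was 1e-05, the smallest that 100000 resamples can give. Scaling by total counts alone in place of TMM moved the median diet difference of all genes from -0.018 to 0.54 on the log2 scale, and the share of called genes that were higher in cdHFD from 49.9% to 88.3%. Directions below are relative to TMM scaling, and a gene or group that turns under total counts is named as such.

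Gpnmb and Mmp12 led the 10 genes that rose furthest in cdHFD livers. Averaged over the 4 times, Gpnmb, a glycoprotein of lipid-laden macrophages (chromosome 6, 49036546 to 49070929), rose from 0.254 to 123 CPM, a log2 fold change of 8.63 ± 0.24 (SE; n = 16 livers per diet). The macrophage elastase gene Mmp12 (chromosome 9, 7344381 to 7369499) rose by 8.52 ± 0.27, from 0.306 to 125 CPM. Lcn2, a secreted iron-carrier protein of the acute phase (chromosome 2, 32384633 to 32388252), rose by 7.13 ± 0.28 from 8.99 to 1011 CPM, and Fgf21, a hormone the liver secretes under nutrient stress (chromosome 7, 45613886 to 45615490), by 6.39 ± 0.28 from 1.58 to 146 CPM. The keratinocyte envelope gene Sprr1a rose by 7.11 ± 0.25, the surface protein gene Ly6d by 6.80 ± 0.30, Vsig8 by 5.93 ± 0.22 and the ubiquitin-like modifier gene Ubd by 5.92 ± 0.33. Vmn2r3, annotated as a vomeronasal receptor, went from 0.0299 to 20.7 CPM and the EGF receptor ligand gene Areg from 0.0286 to 5.81 CPM, with so few counts in chow that their fitted fold changes depend on the prior count.

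The largest decreases were in major urinary protein genes, which encode pheromone carriers secreted by the liver. Mup12 (chromosome 4, 60737383 to 60741326) fell from 2037.5 to 1.001 CPM, a log2 fold change of -11.43 ± 0.46. Mup19, Mup16, Mup10, Mup17, Mup15, Mup11 and Mup14 changed by -10.34 ± 0.63, -9.66 ± 0.57, -9.43 ± 0.84, -9.13 ± 0.68, -9.02 ± 0.60, -8.98 ± 0.38 and -8.05 ± 0.62. Hsd3b5, a male-biased steroid dehydrogenase gene (chromosome 3, 98618634 to 98630252), fell from 219 to 0.481 CPM in males. Sult3a1, a female-biased sulfotransferase gene (chromosome 10, 33857721 to 33879532), went from 82.6 ± 30.1 CPM in chow females to 0.00518 CPM in cdHFD females, where 2 counts remained. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the largest adjusted p among these 20 genes was 1.18e-07, for Mup10. The test called 11092 of 17853 genes, 5530 higher and 5562 lower in cdHFD, and 2402 of the higher and 1301 of the lower ones by at least 2-fold. With total counts alone the same test called 12353 higher and 1632 lower. The Mup genes are near-identical copies, so how reads were shared among them is uncertain, and for genes that differ strongly by sex the fitted value depends on the single sex term of the model.

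Lipid synthesis genes were lower in cdHFD livers. Of 25 genes of cholesterol synthesis and uptake 24 fell. Among them was Sqle, the gene of squalene epoxidase, at -3.91 ± 0.17 (111 to 6.89 CPM). The largest changes were in Idi1 (-4.49 ± 0.39), Fdps (-4.15 ± 0.17) and Tm7sf2 (-4.05 ± 0.11). Of 22 genes of fatty acid and triglyceride synthesis 21 fell, including Fasn (-2.29 ± 0.14), Scd1 (-1.77 ± 0.19), their regulator Srebf1 (-1.08 ± 0.16), Acss2 (-3.05 ± 0.14), Elovl3 (-4.88 ± 0.46) and Thrsp (-3.60 ± 0.24). Both lists were shifted in camera, a competitive gene set test (adjusted p = 2.58e-19 and 1.31e-08 over 42 lists), and each had adjusted p = 0.0741 with an estimated correlation. Under total counts 14 fatty acid synthesis genes were lower and 3 higher, and the cholesterol count of 24 was as before. Lipid droplet genes were higher in 10 and lower in 3 of 18. The droplet-fusing gene Cidec was at 4.05 ± 0.16, Osbpl3 at 3.80 ± 0.21, the fatty acid transporter Cd36 at 2.37 ± 0.16 and the droplet coat gene Plin2 at 0.89 ± 0.12. Camera gave that list adjusted p = 0.0285, and adjusted p = 0.328 with an estimated correlation. Under total counts 15 droplet genes were higher and 2 lower, and the camera call ended (adjusted p = 0.132). Genes of fatty acid oxidation and ketogenesis were split, 8 higher and 9 lower of 26, with Acot2 at 2.80 ± 0.17, Pdk4 at 1.6 ± 0.19 and Cpt1a at 0.68 ± 0.11. Cyp4a14 (-0.08, adjusted p = 0.73 in edgeR's quasi-likelihood test) had the opposite sign under total counts. That list was not shifted (camera adjusted p = 0.897, and adjusted p = 0.981 with an estimated correlation). Its median was -0.11 and its mean 0.33, and under total counts the median turned to 0.45, with 17 higher and 3 lower.

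Of 20 genes of lipoprotein assembly and export 16 were lower and 2 higher, with Apoa2 at -1.62 ± 0.12 and Angptl8 at -1.58 ± 0.40 against Apoa4 at 4.33 ± 0.20. The decreases of Apob (-0.26), Mttp (-0.44) and Tm6sf2 (-0.52) turned to increases under total counts. Bile acid genes were lower in 17 and higher in 3 of 23. The sterol 12-hydroxylase gene Cyp8b1 changed by -3.12 ± 0.34 and the uptake carriers Slc10a1 and Slco1a1 by -2.08 ± 0.15 and -4.75 ± 0.25, and the export subunit gene Slc51b rose by 2.57 ± 0.25. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.56 ± 0.23 with the opposite sign under total counts. Of 30 genes of choline, phosphatidylcholine and one-carbon metabolism 18 fell and 9 rose. Pemt, which methylates phosphatidylethanolamine to phosphatidylcholine, was at -0.60 ± 0.07, Bhmt, which remethylates homocysteine, at -0.80 ± 0.16, Gnmt at -2.28 ± 0.20 and Nnmt at -2.74 ± 0.22, while the serine synthesis genes Psat1 and Phgdh rose by 3.99 ± 0.16 and 2.995 ± 0.289. Glucose and glycogen genes were lower in 14 and higher in 2 of 21, with the gluconeogenic genes G6pc at -1.25 ± 0.26 and Pck1 at -0.84 ± 0.30, Ppp1r3c at -1.58 ± 0.26, Ppp1r3g at 1.56 ± 0.57 and Igfbp1 at 2.44 ± 0.58. That list's median of -0.50 turned to 0.07 under total counts, with 8 genes higher and 5 lower. Under that scaling the splits of higher to lower were 5 to 8 for lipoproteins, 5 to 12 for bile acids and 12 to 13 for choline. Camera adjusted p was 3.08e-04 for lipoproteins, 1.72e-04 for bile acids, 0.00525 for choline and 0.00542 for glucose, and with an estimated correlation adjusted p = 0.114, 0.137, 0.227 and 0.137. Adjusted over the list alone, the counts of these 8 lists were the same except for lipid droplets (10 higher, 4 lower), bile acids (4 higher, 17 lower) and choline (9 higher, 19 lower).

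**Figure D1:**
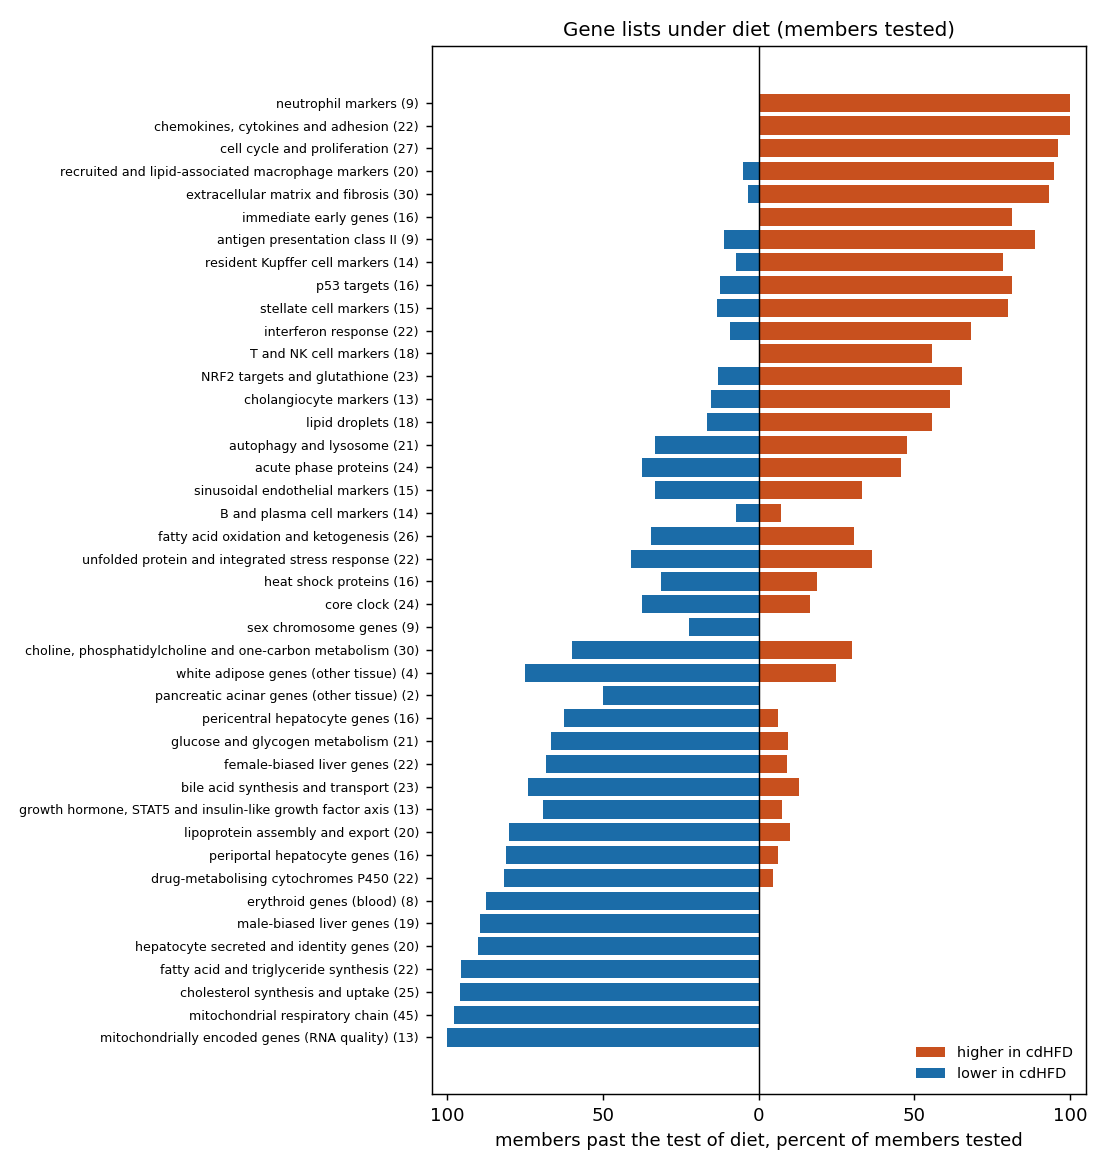
Percent of the tested members of each gene list (horizontal axis) that were higher or lower in cdHFD than in chow livers by edgeR's quasi-likelihood test at adjusted p under 0.05, with 1 bar per list and direction and n = 16 libraries per diet. Of the 22 chemokine, cytokine and adhesion genes all were higher and of the 25 cholesterol genes 24 were lower; under scaling by total counts the medians of the core clock, fatty acid oxidation, glucose, unfolded protein, heat shock and sex chromosome lists turn to above 0.

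Matrix and inflammatory genes were higher in cdHFD livers. Of 30 genes of extracellular matrix and fibrosis 28 rose and 1 fell. The collagen gene Col1a1 rose by 3.04 ± 0.25 (22.6 to 186 CPM), the protease inhibitor gene Timp1 by 5.04 ± 0.30 and the collagenase gene Mmp13 by 4.497 ± 0.299, whereas Acta2, the smooth muscle actin of activated stellate cells, was at 0.86 ± 0.48 (adjusted p = 0.126 in edgeR's quasi-likelihood test). In chow Acta2 lay at 144 CPM in ZT2 replicate 4 and 76.4 CPM in ZT14 replicate 2. Without the first of these it was 1.36 higher in cdHFD (adjusted p = 0.00877 in edgeR) and without the second 1.795, and both calls passed. Stellate cell markers were higher in 12 and lower in 2 of 15, with Lrat at 0.90 ± 0.14, Pdgfrb at 1.15 ± 0.11, Pdgfra at 1.39 ± 0.12 and Hgf at 1.6 ± 0.22. All 22 genes of chemokines, cytokines and adhesion rose. Among them were Ccl2 (4.42 ± 0.16) and Ccl3 (3.90 ± 0.34), which attract monocytes, the neutrophil attractant gene Cxcl2 (3.84 ± 0.17), Tnf (3.09 ± 0.24) and Il1b (1.26 ± 0.17). The lipid-associated macrophage list was higher in 19 and lower in 1 of 20, with Trem2, a lipid-sensing receptor, at 5.38 ± 0.16 (1.03 to 44.2 CPM) and Cd68 at 2.79 ± 0.13. Markers of resident Kupffer cells were higher in 11 and lower in 1 of 14, including Cd5l (2.77 ± 0.18), Marco (2.75 ± 0.27), C1qb (2.09 ± 0.16), Vsig4 (1.64 ± 0.16), Clec4f (1.08 ± 0.14) and Timd4 (0.74 ± 0.14). All 9 neutrophil markers tested of the 14 listed rose, with the alarmin genes S100a8 and S100a9 at 3.07 ± 0.26 and 2.83 ± 0.27. In camera adjusted p was 1.19e-12 for matrix, 0.00171 for stellate cells, 6.45e-14 for chemokines, 3.34e-13 for macrophages, 6.62e-05 for Kupffer cells and 7.14e-06 for neutrophils. Of these only the chemokine call held with an estimated correlation (adjusted p = 0.0325), and for the others adjusted p = 0.137, 0.137, 0.0576, 0.197 and 0.0877 with an estimated correlation. With an estimated correlation and total counts together the chemokine call ended too (adjusted p = 0.0618). Under total counts 14 stellate markers were higher and 0 lower. The counts of these 6 lists were the same adjusted over the list alone.

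Other immune genes moved less uniformly. T and NK cell markers were higher in 10 of 18, with Ncr1 at 1.6 ± 0.32, Ccr7 at 1.35 ± 0.19, Prf1 at 1.34 ± 0.28 and Cd8a at 0.95 ± 0.28, and the T cell receptor gene Cd3e at 0.13 (adjusted p = 0.528 in edgeR's quasi-likelihood test). Class II antigen presentation genes rose in 8 of 9, with H2-Aa at 1.79 ± 0.14, Cd74 at 1.78 ± 0.14, H2-Ab1 at 1.69 ± 0.15 and the lysosomal protease gene Ctss at 2.94 ± 0.17, and 1 fell. Interferon response genes were higher in 15 and lower in 2 of 22, led by Oas1a (1.99 ± 0.16), Oasl2 (1.84 ± 0.15) and Ifit2 (1.72 ± 0.13). Isg15 was at 0.71 ± 0.15, Irf7 at 0.74 ± 0.12 and Ifit1 at 0.27 (adjusted p = 0.149 in edgeR's quasi-likelihood test, and 0.40 with adjusted p = 0.0223 without chow ZT8 replicate 2). Acute phase genes were split, 11 higher and 9 lower of 24, with Saa1 (2.16 ± 0.18), Saa3 (2.69 ± 0.19), Orm2 (2.15 ± 0.19) and Lcn2 higher, and under total counts 15 were higher and 4 lower. Camera adjusted p was 0.0285 for T and NK cells, 6.62e-05 for class II genes, 7.98e-04 for interferon and 0.363 for acute phase genes, and with an estimated correlation adjusted p = 0.481, 0.164, 0.28 and 0.747. Under total counts the T and NK cell call ended (camera adjusted p = 0.325), and 16, 9 and 20 genes of the first 3 lists were higher and 0 lower. The counts of these 4 lists were the same adjusted over the list alone, except for acute phase genes (11 higher, 10 lower).

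Genes that mark hepatocytes were lower in the same cdHFD livers in which the median lipid-associated macrophage marker was 2.86 higher. Of 20 hepatocyte secreted and identity genes 18 fell. Among them were Alb (-1.31 ± 0.07), Ttr (-1.59 ± 0.08), the transcription factor genes Hnf4a (-0.78 ± 0.06) and Onecut1 (-1.80 ± 0.25), Hpd (-1.88 ± 0.11) and Serpina1c (-2.61 ± 0.12). Genes of periportal hepatocytes were lower in 13 and higher in 1 of 16, with Cyp2f2 at -2.35 ± 0.17, Hal at -2.57 ± 0.13, Gls2 at -1.96 ± 0.13 and Etnppl at -2.67 ± 0.20. Genes of pericentral hepatocytes were lower in 10 and higher in 1 of 16, with Glul at -0.81 ± 0.09, Cyp2e1 at -1.13 ± 0.12, Cyp1a2 at -0.66 ± 0.12, Rgn at -1.78 ± 0.11, Oat at -1.65 ± 0.18 and Cyp2c29 at -2.62 ± 0.27. Drug-metabolising cytochromes P450 were lower in 18 and higher in 1 of 22, including Cyp2c54 (-4.96 ± 0.16), Cyp3a16 (-3.68 ± 0.42), Cyp2b10 (-1.77 ± 0.48) and Cyp3a11 (-1.08 ± 0.20). How reads were shared among the P450 paralogs is uncertain. Under total counts the split of higher to lower calls became 3 to 13 for hepatocyte identity, 3 to 10 for periportal, 7 to 6 for pericentral and 2 to 12 for P450 genes. The identity list was shifted in camera with either correlation (adjusted p = 1.66e-09, and adjusted p = 0.0393 with an estimated correlation). Under total counts that was adjusted p = 5.50e-04. The periportal, pericentral and P450 lists had camera adjusted p = 1.22e-05, 0.00653 and 5.34e-05, and with an estimated correlation adjusted p = 0.114, 0.227 and 0.118, where total counts gave 0.00724, 0.118 and 0.00724. With p adjusted over the list alone, 19 identity genes fell and the P450 genes were 1 higher and 19 lower, and the zonation counts were the same.

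Genes of the growth hormone, STAT5 and insulin-like growth factor axis were lower in 9 and higher in 1 of 13, with the growth hormone receptor gene Ghr at -1.75 ± 0.10, Igf1 at -1.40 ± 0.09, Igfals at -2.05 ± 0.13, Egfr at -2.19 ± 0.24 and Prlr at -1.76 ± 0.18. Nuclear genes of the mitochondrial respiratory chain were lower in 44 of 45, with Ndufa1 at -0.63 ± 0.10, Cox5b at -0.65 ± 0.12, Ndufb5 at -0.90 ± 0.07, Ndufb9 at -1.07 ± 0.10. Atp5b, at -0.37 ± 0.12, turned under total counts. All 13 mitochondrially encoded genes fell, among them mt-Nd1 (-1.01 ± 0.13), mt-Co1 (-1.33 ± 0.10), mt-Cytb (-1.22 ± 0.11) and mt-Atp6 (-1.62 ± 0.27). Under total counts the split of higher to lower calls was 4 to 5 for the growth hormone axis and 4 to 6 for the respiratory chain, whose median went from -0.60 to -0.029, while 12 of the mitochondrially encoded genes were lower. Camera adjusted p was 0.00185 for the growth hormone axis, 8.18e-12 for the respiratory chain and 3.27e-06 for the mitochondrially encoded genes, and with an estimated correlation adjusted p = 0.103, 0.137 and 0.164. The counts of these 3 lists were the same adjusted over the list alone.

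Proliferation and damage response genes were higher in cdHFD livers. Of 27 cell cycle genes 26 rose, including Mki67 (3.14 ± 0.19), Top2a (3.43 ± 0.21), Bub1 (3.52 ± 0.26), Ccnb1 (3.67 ± 0.39) and Ccnd1 (1.59 ± 0.25). Of 16 p53 targets 13 rose and 2 fell, with the cell cycle inhibitor gene Cdkn1a at 3.64 ± 0.23 (9.90 to 82.1 CPM), Eda2r at 3.56 ± 0.25, Phlda3 at 3.27 ± 0.13, Gdf15 at 1.91 ± 0.32 and Mdm2 at 0.43 ± 0.07. Of 16 immediate early genes 13 rose, among them Fos (2.49 ± 0.20), Fosb (2.57 ± 0.28), Jun (2.33 ± 0.12), Klf6 (2.53 ± 0.13) and Egr1 (2.03 ± 0.35). NRF2 targets and glutathione genes were higher in 15 and lower in 3 of 23, with the quinone reductase gene Nqo1 at 1.47 ± 0.12, Hmox1 at 2.57 ± 0.13, Cbr3 at 4.19 ± 0.24 and Gsta1 at 2.99 ± 0.37. Gclc (-0.11, adjusted p = 0.326 in edgeR's quasi-likelihood test) had the opposite sign under total counts. Camera adjusted p was 1.29e-11 for the cell cycle, 7.40e-05 for p53 targets, 1.39e-05 for immediate early genes and 0.00171 for NRF2 targets. The p53 call held with an estimated correlation (adjusted p = 0.0122) but not with that correlation and total counts together (adjusted p = 0.0618), and for the others adjusted p = 0.103, 0.0561 and 0.137 with an estimated correlation. Under total counts 16 p53 targets and 21 NRF2 targets were higher and 0 lower. Adjusted over the list alone, 27 cell cycle genes rose and the counts of the other 3 lists were the same.

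The unfolded protein and integrated stress response list was split, 8 higher and 9 lower of 22. Its members that rose included Atf3 (3.96 ± 0.15), Nupr1 (3.30 ± 0.23), Asns (2.81 ± 0.32), which makes asparagine, Trib3 (2.60 ± 0.20) and Ddit3 (0.87 ± 0.17). The chaperone gene Hspa5 was at -0.17 (adjusted p = 0.185 in edgeR's quasi-likelihood test) and had the opposite sign under total counts. Heat shock protein genes were higher in 3 and lower in 5 of 16, with Hspa1a at 2.08 ± 0.37, Hspa1b at 0.85 ± 0.28 and the cold-induced gene Rbm3 at 0.79 ± 0.08. The values of Hspa8 (-0.12) and Dnajb1 (-0.030), neither of them called, turned under total counts. Autophagy and lysosome genes were higher in 10 and lower in 7 of 21, with the lysosomal genes Ctsd (1.18 ± 0.06) and Hexa (0.98 ± 0.07) higher. Sqstm1 was at 0.58 ± 0.09, Lamp1 at 0.35 ± 0.12 and Ulk1 at -0.53, which turned under total counts. These 3 lists were not shifted in camera (adjusted p = 0.70, 0.701 and 0.594, and with an estimated correlation adjusted p = 0.905, 0.905 and 0.892). The stress list had a median of -0.15 and a mean of 0.54, and the heat shock list a median of -0.075 and a mean of 0.13. Under total counts the medians turned to 0.42 and 0.49, with 15 genes higher in each. Their counts were the same adjusted over the list alone, except for autophagy (10 higher, 9 lower), and under total counts 16 autophagy genes were higher and 1 lower.

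Diet differences were also tested at each time. The test called 7446 genes at ZT2 (3746 higher, 3700 lower), 7149 at ZT8 (3683, 3466), 6352 at ZT14 (3540, 2812) and 6972 at ZT20 (3530, 3442), with n = 4 livers per group. Under total counts the splits of higher to lower were 8627 to 1326, 9512 to 984, 8644 to 872 and 9041 to 1172. For 1030 genes the diet effect differed between the times (3 df quasi-likelihood test). These included 15 of 24 core clock genes, 11 of 16 heat shock genes and 10 of 27 cell cycle genes (Fisher's exact test, adjusted p = 7.95e-12, 1.57e-09 and 1.87e-05). The clock output gene Dbp was 5.81 ± 0.88 higher in cdHFD at ZT2 and at -1.04, -1.61 and -1.63 at the later times, none of which passed. Within the cdHFD ZT2 group Dbp lay at 1.75 and 3.44 CPM in the males and at 76.4 and 191 CPM in the females, against 0.978 CPM ± 0.370 in chow. Cdkn1a was higher in cdHFD by 4.98 at ZT8 and 5.03 at ZT14 but by 2.09 ± 0.45 at ZT2 and 2.45 at ZT20. Fgf21 was higher by 5.8 ± 0.56, 4.85, 7.48 and 7.42 at the 4 times in order, the transporter gene Abcc12 by 5.92 ± 0.39, 2.75, 3.27 and 3.61, and Atf3 by 4.20 ± 0.31, 4.85, 2.97 and 3.80. Slc51b reached 4.81 at ZT14 against 1.44 ± 0.49 at ZT2. For each of these genes the SE was the same at ZT2, ZT8 and ZT20 and at ZT14 within 0.01 of it.

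Among genes that were lower, Thrsp, a regulator of lipogenesis, changed by -4.06 ± 0.47, -1.61, -2.69 and -6.05 at ZT2, ZT8, ZT14 and ZT20. The uridine phosphorylase gene Upp2 did not pass at ZT2 (-0.55) and changed by -2.24, -3.58 and -3.73 ± 0.50 at the later times. The receptor subunit gene Chrna4 changed by -6.77 ± 0.47, -5.87, -3.30 and -5.28, and Mup12 by -13.82 ± 0.92, -9.01, -11.78 and -11.12. Without cdHFD ZT8 replicate 2 the ZT8 value of Mup12 was -12. Its smaller fall at ZT8 than at ZT14 and ZT20 thus rested on that library. Hnf4aos changed by -4.93 ± 0.31, -3.93, -3.36 and -4.79. It lies antisense to Hnf4a and the libraries do not mark strand, so reads from any stretch where they overlap cannot be told apart. The mitotic genes Ube2c and Cdc20 were higher by 5.08 and 5.05 at ZT20 against 2.04 and 1.12 at ZT8, where Cdc20 did not pass. In edgeR's quasi-likelihood test of diet by time with Benjamini-Hochberg adjustment, adjusted p for these 13 genes ran from 8.92e-04 (Thrsp) to 0.0477 (Mup12). The count of 1030 rose to 2065 without chow ZT2 replicate 4 and to 1958 without cdHFD ZT2 replicate 4, and was 2146 with DESeq2 and 2639 without the filter on low counts.

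Clock genes were among those with the largest daily rhythms in chow livers, ranked among genes with a mean of at least 5 CPM. Dbp had an amplitude of 4 ± 0.54 on the log2 scale (from mean to peak, SE) with its peak at ZT 11.1 ± 0.52 h, and Npas2 one of 3.60 ± 0.36 with its peak at 23.97 ± 0.38 h. Nr1d1, which encodes REV-ERB alpha, had 3.33 ± 0.39 at 8.87 ± 0.45 h, Ciart 3.25 ± 0.36 at 11.9 ± 0.43 h and Arntl, which encodes BMAL1, 2.67 ± 0.31 at 22.3 ± 0.44 h. Beyond the clock list the largest amplitudes were those of Rgs16 (3.25 ± 0.44), Clic3 (2.59 ± 0.36), Slc34a2 (2.56), Loxl4 (2.53) and the tubulin gene Tubb2b (2.46 ± 0.25). A 24 h rhythm passed edgeR's quasi-likelihood test in 3164 of 17853 genes in chow (17.7%), and adjusted p for these 10 genes was at most 2.13e-04, that of Dbp. Of the rhythmic genes 757 peaked from ZT 0 to 6, 855 from 6 to 12, 549 from 12 to 18 and 1003 from 18 to 24. They included 20 of 24 core clock genes, 12 of 16 heat shock genes, 10 of 21 glucose genes, 10 of 22 interferon genes and 7 of 14 B cell genes (Fisher's exact test, adjusted p = 1.90e-10, 1.77e-05, 0.0166, 0.0205 and 0.0409). Adjusted over the list alone, these counts were 20, 15, 13, 12 and 10. A contrast of ZT2 and ZT14 against ZT8 and ZT20, which a 24 h rhythm does not need, passed for 1883 genes in chow and 196 in cdHFD, of which 278 and 7 also passed the 24 h test. Over the 4 times in order, mean total counts in chow were 33.1, 44.1, 33.3 and 38.5 M and mean mitochondrial shares 8.89%, 6.54%, 10.03% and 7%. In cdHFD they alternated likewise, at 39.3, 45.3, 31.5 and 38.6 M and 5.49%, 4.51%, 5.98% and 4.48%. Any difference between the 4 times passed for 5732 genes in chow.

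In cdHFD livers 441 genes passed the rhythm test (2.47%), of which 302 had also passed in chow, where independent lists would share 78.2. By peak time they numbered 10, 189, 35 and 207 in the same parts of the day. Rhythms differed between the diets in 649 genes, among them 133 of those 302, 438 of the 2862 called only in chow and 50 of the 139 called only in cdHFD. The test of that difference does not separate amplitude from timing. The tubulin genes Tubb2b and Tubb2a fell in amplitude from 2.46 ± 0.25 to 0.60 and from 1.76 ± 0.16 to 0.55, Cdkn1a from 1.91 ± 0.25 to 0.54 ± 0.25, the nuclear receptor gene Ppard from 1.74 ± 0.18 to 0.48, the heat shock gene Hspb1 from 1.38 ± 0.17 to 0.21 and the receptor kinase gene Grk5 from 1.31 ± 0.10 to 0.15 ± 0.10. Clic3 went from 2.59 to 0.58, Atp2b2 from 2.11 to 0.84, Paxx from 1.58 to 0.37 and Col20a1 from 1.28 to 0.068. These amplitudes are on the log2 scale. In CPM the range of the group means was larger in cdHFD for Tubb2b, Tubb2a and Cdkn1a and smaller for the other genes named here. Cdkn1a, for example, ran from 1.55 to 18.7 CPM in chow and from 50.1 to 122 CPM in cdHFD. Among 2696 genes past a joint test of rhythm in either diet 2221, or 82.4%, had a smaller amplitude in cdHFD (medians 0.48 in chow and 0.27 in cdHFD), and among the 302 the share was 66.9% (medians 0.76 and 0.65). The share was 69.7% over all 17853 genes tested, rhythmic or not (medians 0.27 and 0.18), and 45.8% among the 441 genes past the cdHFD test. The adjusted p of the difference ran from 1.96e-04 (Grk5) to 0.0391 (Clic3) for these 10 genes in edgeR's quasi-likelihood test. Over 32 fits that each left out 1 library, the call was kept in 9 for Clic3 and 25 for Atp2b2. The count of 649 became 1179 without chow ZT14 replicate 2, 1131 without cdHFD ZT2 replicate 4, 431 without cdHFD ZT8 replicate 4, 1310 with DESeq2 and 1809 without the filter. That of 441 became 280, 285 and 279 without cdHFD ZT8 replicate 2, ZT20 replicate 3 and ZT20 replicate 4. Any difference between the 4 times passed for 970 genes in cdHFD.

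Several cell cycle genes had larger fitted amplitudes in cdHFD than in chow livers, though amplitude was not tested apart from timing. Mcm6, part of the replicative helicase, rose in amplitude from 0.22 to 0.97 ± 0.16 with its cdHFD peak at ZT 10.5, and its regulator E2f1 from 0.086 to 0.83 ± 0.13 (10.7). Uhrf1, a cofactor of maintenance DNA methylation, rose from 0.48 to 1.19 ± 0.23 (9.38) and the DNA polymerase gene Pole from 0.10 to 0.81 (11.5). The mitotic genes Plk1, Cdc20 and Ckap2 and the cytokinesis gene Iqgap3 rose from 0.37 to 1.18 ± 0.28 (19.6), 0.63 to 1.33 ± 0.36 (20.2), 0.45 to 1.21 (20.3) and 0.32 to 1.06 (18.4). Mean Mcm6 in cdHFD was 23.4 CPM ± 5.49, 48.9 ± 3.96, 49.7 ± 11.5 and 16.9 ± 2.80 (SD, n = 4) at ZT2, ZT8, ZT14 and ZT20, and mean Plk1 was 10.2 ± 9.12, 5.21 ± 1.37, 8.62 ± 0.949 and 26.2 ± 4.06. Thrsp, from 1.01 ± 0.23 to 2.27 ± 0.23, and Slfn9, from 0.093 to 0.97, completed the 10 largest rises. Of 27 cell cycle genes 3 were rhythmic in chow, 19 in cdHFD and 9 differed between diets, and adjusted over the list alone 3, 25 and 20 (Fisher's exact test, adjusted p = 1.53e-23 for the cdHFD count and 3.83e-06 for the difference). The adjusted p of the difference for the 10 genes ran from 5.57e-04 (Thrsp) to 0.0491 (Iqgap3) in edgeR's quasi-likelihood test. Over 32 fits that each left out 1 library, the call was kept in 31 for Plk1 and Cdc20 (lost without chow ZT8 replicate 3, adjusted p = 0.0536 and 0.0683), 17 for Slfn9, 10 for Ckap2, 8 for Pole and 7 for Iqgap3.

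**Figure D2:**
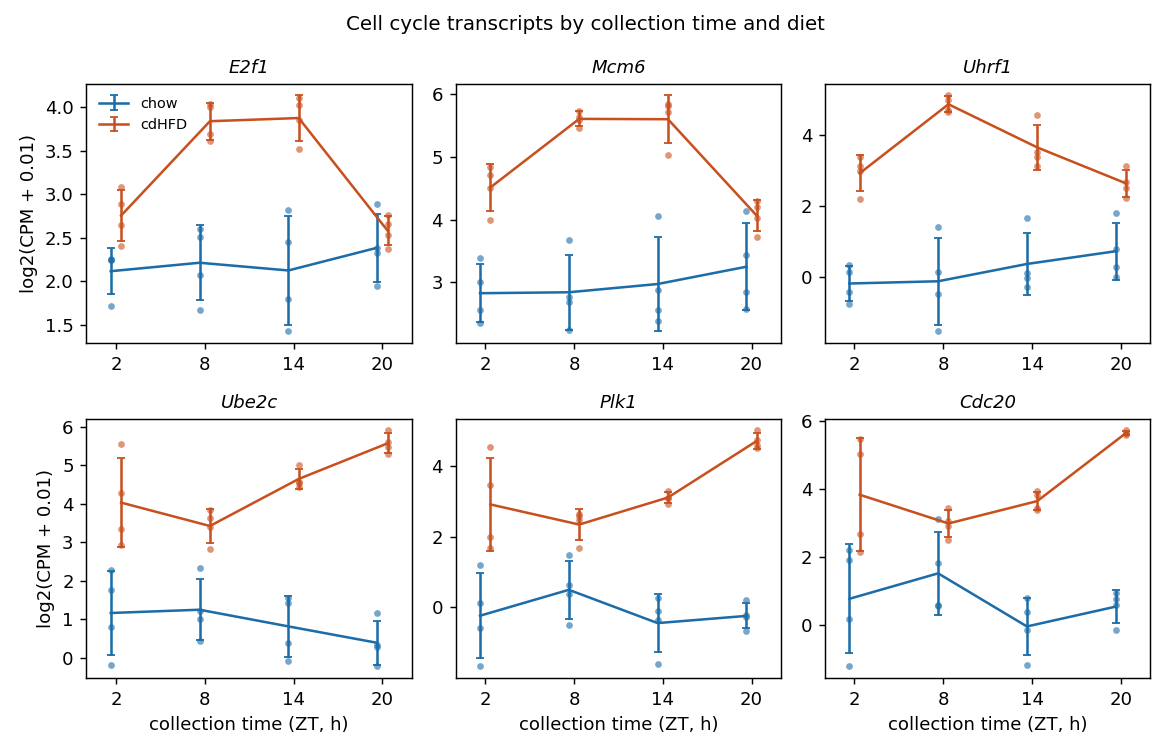
log2(CPM + 0.01) of E2f1, Mcm6, Uhrf1, Ube2c, Plk1 and Cdc20 (vertical axis) against zeitgeber time in h (horizontal axis) in chow and cdHFD livers; points are libraries, lines join group means and bars are SD (n = 4). In cdHFD the mean of Mcm6 was 48.9 CPM at ZT8 and 16.9 CPM at ZT20, and that of Plk1 5.21 CPM at ZT8 and 26.2 CPM at ZT20.

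Most core clock genes were rhythmic in cdHFD livers and peaked earlier than in chow. Of 24 core clock genes 16 passed the rhythm test in cdHFD and 10 differed between diets (20 and 18 adjusted over the list alone). Arntl peaked at 20.05 ± 0.55 h in cdHFD against 22.3 ± 0.44 h in chow, Npas2 at 21.4 ± 0.46 against 23.97 ± 0.38 h, Nr1d1 at 6.51 ± 0.65 against 8.87 ± 0.45 h and Dbp at 7.89 ± 0.69 against 11.1 ± 0.52 h. Per2, a repressor of the clock, went from 15.5 ± 0.68 to 10.4 ± 0.53 h with its amplitude at 1.33 ± 0.24 in chow and 1.72 ± 0.24 in cdHFD. Per1 went from 12.4 to 9.64 h, Nr1d2 from 10.7 to 7.91 h, Tef from 12.1 to 9.01 h, Usp2 from 12.7 to 10.1 h and Hlf from 12.95 to 9.70 h. Cry1 was rhythmic in chow (1.45) and did not pass in cdHFD (0.88, adjusted p = 0.126 in edgeR's quasi-likelihood test). Of the 302 genes rhythmic in both diets 289 (95.7%) peaked earlier in cdHFD, by a median of 3.12 h, and 16 of 16 core clock genes by 2.74 h. The largest shifts were those of Cenpa (7.22 to 20.5 h), Mospd1 (10.99 to 0.333 h), Dtymk (21.9 to 12.1 h), Wnt5b (18.1 to 9.42 h) and Fkbp4 (20.1 to 11.4 h). In edgeR's quasi-likelihood test of the difference, adjusted p was 0.00335 for Per2, 0.0166 for Nr1d1, 0.0223 for Nr1d2, 0.0255 for Ciart, 0.03 for Npas2 and Usp2, 0.037 for Hlf, 0.00803 for Timeless and 0.0491 for Bhlhe41. Timeless did not show the common advance, as its mean was highest at ZT2 in chow (11.55 CPM) and at ZT8 in cdHFD (17.1 CPM). Not all clock genes with an earlier fitted peak passed the test of the difference, and Dbp (0.0693) and Arntl (0.10) did not.

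**Figure D3:**
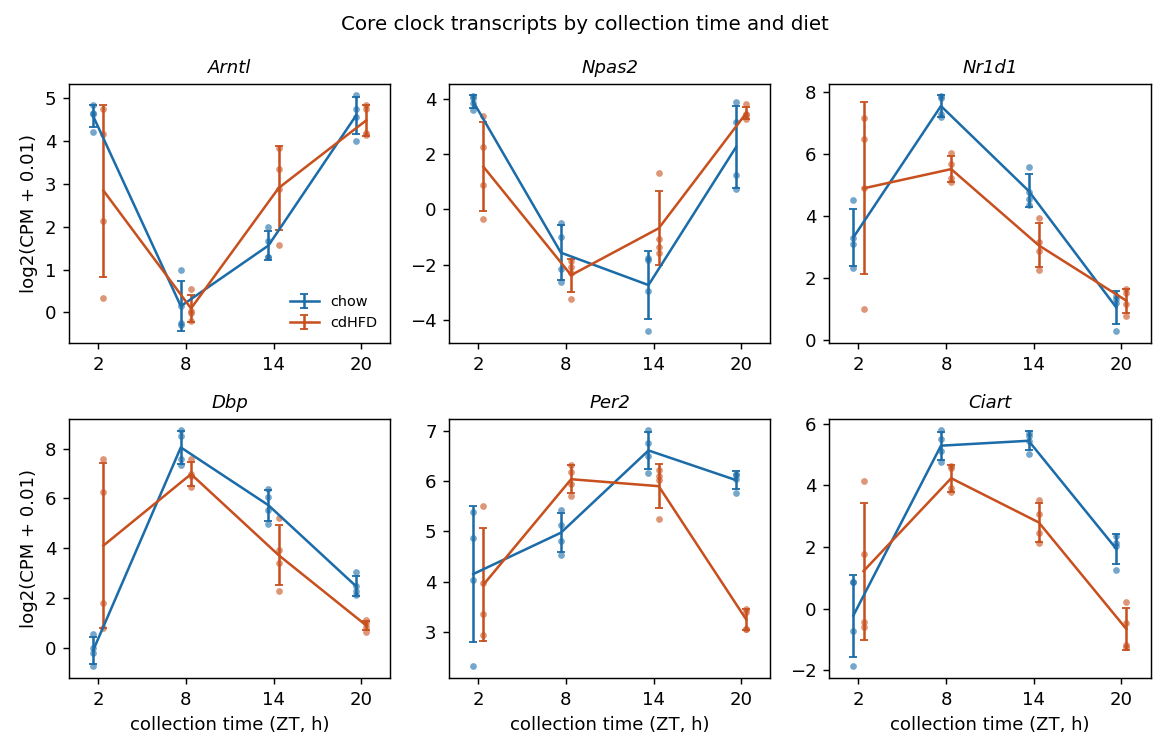
log2(CPM + 0.01) of Arntl, Npas2, Nr1d1, Dbp, Per2 and Ciart (vertical axis) against zeitgeber time in h (horizontal axis) in chow and cdHFD livers; points are libraries, lines join group means and bars are SD (n = 4). Fitted peaks in cdHFD were earlier, as for Per2 at 10.4 h against 15.5 h in chow, and at ZT2 the 4 cdHFD libraries of Dbp ran from 1.75 to 191 CPM.

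Averaged over the times, clock gene levels differed little in a common direction, with 4 higher and 9 lower of 24 in cdHFD (camera adjusted p = 0.166, and adjusted p = 0.331 with an estimated correlation; the counts were the same adjusted over the list alone). The median of -0.21 turned to 0.36 under total counts, with 11 higher and 2 lower, and camera then called the list lower relative to other genes (adjusted p = 0.0183, and adjusted p = 0.175 with an estimated correlation). Cry1, which turned to 0.23 under total counts, was at -0.34 (adjusted p = 0.175 in edgeR) and at -0.58 without cdHFD ZT2 replicate 1 (adjusted p = 6.60e-04). To place each liver on the clock, the 20 clock genes rhythmic in chow were matched to their chow curves. The clock of cdHFD livers read a median of 4 h ahead of the collection time and that of chow livers -0.05 h, with each chow library left out of its own curve (difference 4.05 h, n = 16 each, two-sided permutation p = 2.10e-04). Of the 16 cdHFD livers 15 read ahead. The group medians in cdHFD were 3, 4.20, 2.75 and 4.5 h at ZT2, ZT8, ZT14 and ZT20, a range of 1.75 h (permutation p = 0.533). At ZT2 the 4 cdHFD livers read -3, 1.70, 4.30 and 6.90 h. The mean lead of 3.45 h (SD 2.27) was below the 6 h between collections (exact two-sided sign-flip test, p = 1.22e-04, n = 16), with 15 of 16 livers below it. Without the ZT2 females (replicates 3 and 4), left out after the data were seen, the median advance was 2.41 h over 379 genes rhythmic in both diets.

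**Figure D4:**
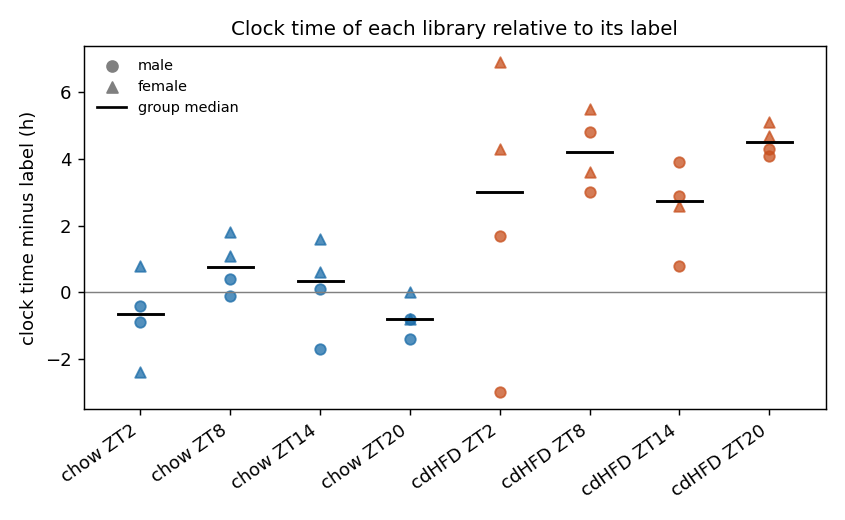
Lead in h of the clock reading over the collection time (vertical axis) for each library by group (horizontal axis), males as circles and females as triangles, with a bar at each group median. The cdHFD medians lie between 2.75 and 4.5 h and the chow medians between -0.80 and 0.75 h.

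Male and female livers differed less in cdHFD than in chow. In chow males the fatty acid hydroxylase gene Cyp4a12a (chromosome 4, 115299046 to 115332815) stood at 439 CPM ± 52.4 (SD, n = 8) and in chow females at 0.564. In cdHFD males it fell to 11.9 CPM ± 7.08 (n = 9). Mup7 fell from 3551 to 7.77 CPM and Cyp4a12b from 134 to 7.74 CPM in males. Mup20 fell from 3804 to 1268 CPM in males and rose from 58.9 to 612 CPM in females, so that the female minus male difference went from -6.00 ± 0.23 to -0.99 ± 0.24 on the log2 scale. In the other direction the cytochrome P450 gene Cyp2b9 (chromosome 7, 26173411 to 26210661) went from 414 to 75.6 CPM in females and 0.438 to 9.15 CPM in males, and Cyp2a4 from 1819 to 946 CPM in females and 4.59 to 211 CPM in males. Females also fell in Cyp2b13 (326 to 36.9 CPM), Sult2a2 (235 to 58.0), A1bg (115 to 1.63), Cyp3a41b (68.7 to 0.91) and Cyp3a44 (44.0 to 2.19). Males fell in Mup21 (285 to 5.67), C4a (138 to 8.71), Nat8f5 (55.2 to 9.44) and Slc22a28 (20.6 to 0.339). The Y-linked genes Eif2s3y (-9.25 in chow, -9.15 in cdHFD) and Ddx3y (-9.22, -9.07) and Xist (11.06, 10.66) differed by sex in both diets. Kdm5d, also Y-linked, lay at 14.4 CPM in chow males and 11.1 CPM in cdHFD males, with 1 and 3 counts in all in the females.

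In edgeR's quasi-likelihood test 1691 genes differed by sex in chow (1092 higher in females, 599 in males) and 168 in cdHFD (92 and 76), sharing 129, where independent lists would share 15.9. The sex difference itself changed with diet in 331 genes, and for 309 of them it was smaller in cdHFD. Among 1236 autosomal genes past the sex effect averaged over both diets 87.3% had a smaller difference in cdHFD (median size 0.78 in chow, 0.33 in cdHFD). The larger residual spread of chow libraries could raise the chow sizes. With 1 estimate of spread shared by both diets, it could also raise the chow count and lower that of cdHFD. For Cyp4a12a the female minus male difference rose by 5.66 ± 0.57 (adjusted p = 3.40e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), for Mup20 by 5.01 ± 0.34 (8.98e-12) and for Cyp2b9 it changed by -6.28 ± 0.95 (8.31e-05). The fixed list of female-biased liver genes had 22 of 22 higher in females in chow and 15 in cdHFD (median 8.42 and 2.52), and the male-biased list 19 of 19 and 14 higher in males (median -3.73 and -2.37). The interaction passed for 15 of the female-biased genes, all negative, and 8 of the male-biased genes, all positive (21 and 13 adjusted over the list alone). Both list shifts held with an estimated correlation in camera (adjusted p = 1.36e-51 and 1.97e-32, and adjusted p = 2.18e-05 and 0.00114 with an estimated correlation). Averaged over times, 17 of 19 male-biased genes fell in cdHFD (camera adjusted p = 5.19e-10, and adjusted p = 0.127 with an estimated correlation). Of 22 female-biased genes 15 fell, among them Cyp2c69 at -5.60 ± 0.47, and 2 rose (camera adjusted p = 0.023, and adjusted p = 0.599 with an estimated correlation). Both counts were the same adjusted over the list alone. In 32 fits that each left out 1 library the interaction was kept in 30 for Mup7 and Sult3a1 and 31 for Cyp3a41b. It was lost without cdHFD ZT14 replicate 4 for all 3, and also without cdHFD ZT2 replicate 4 for Mup7 and ZT14 replicate 2 for Sult3a1. The count of 331 was 211 without the ZT2 cdHFD females, 613 with DESeq2 and 798 without the filter.

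**Figure D5:**
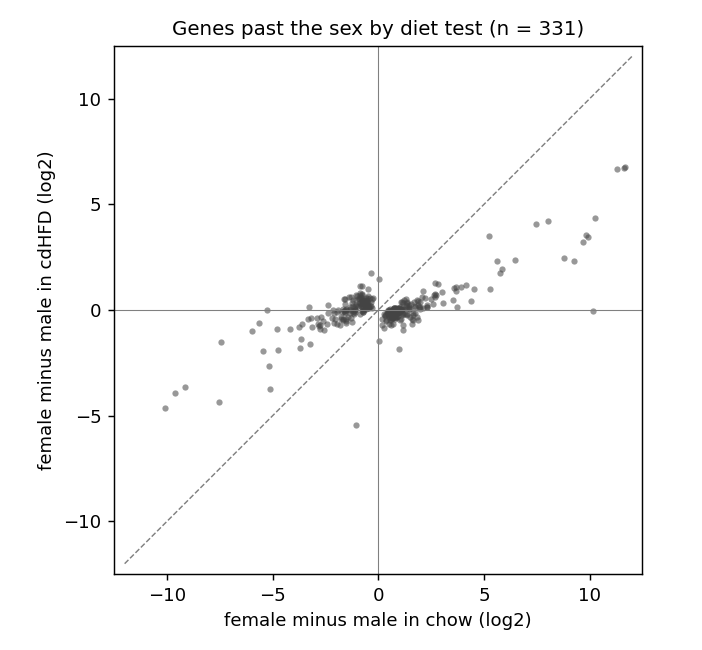
Female minus male log2 difference in chow (horizontal axis) and in cdHFD (vertical axis) for the 331 genes whose sex difference changed with diet, 1 point per gene, with a dashed line where both are equal. For 309 of the 331 the difference was smaller in cdHFD, as for Mup20 at -6.00 in chow and -0.99 in cdHFD.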

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

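Of the tests in this part, the one of whether 2 libraries blurred the cdHFD rhythm and the 13 counts over other splits of the libraries were set before their results were seen. The 2 libraries of the first test were themselves chosen after the data were seen. The other 8, on shifted time labels, libraries that ran ahead, late collection, sex labels, spread between libraries (for sex and for rhythm), dilution by other cells and technical differences among the chow times, were chosen only after the result was seen.

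Of the 302 genes rhythmic in both diets 289 peaked earlier in cdHFD, by a median of 3.12 h. If cdHFD time labels were off by 1 collection interval, clock readings would lie about 6 h ahead, but their median lead was 4 h and 15 of 16 livers lay below 6 h (exact sign-flip p = 1.22e-04). The 2 cdHFD ZT2 libraries that ran ahead of the other 2 did not carry the advance, since the median without them was 2.41 h and 331 of 379 genes were earlier. If all cdHFD mice had been collected later than their labels by the same time, every group would show the same lead. The group medians differed by 1.75 h (permutation p = 0.533), which leaves that open. The spread of the 4 cdHFD ZT2 livers, from -3 to 6.9 h (SD 4.22), limits what this test can show. An effect of the diet on clock phase is open as well, and these data do not separate the 2.

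Fewer genes differed by sex in cdHFD (168) than in chow (1691). Mislabelled sex of libraries was argued against by Xist and the Y-linked genes, which went against the label in 0 of the 32 libraries. A larger spread between cdHFD libraries was argued against by their median residual SD of 0.311, below the 0.377 of chow, while the median size of the sex difference went from 0.78 to 0.33. The larger chow spread could raise the sizes fitted in chow. With 1 estimate of spread shared by both diets, it could also add calls in chow and remove them in cdHFD. Both stay open. Dilution by RNA of other cells was argued against because the median log2 change of the male-biased list in males (-4.39) was 4.46 times that of the hepatocyte list (-0.985), and that of the female-biased list in females (-2.88) was 2.58 times (-1.12). With these 3 set aside, a hypothesis is that the diet may act on sex-dependent transcription in the liver. It arose from these same livers, and no test here could decide it.

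Fewer genes were rhythmic in cdHFD (441) than in chow (3164), and 82.4% of rhythmic genes had the smaller amplitude in cdHFD, against 69.7% of all genes tested and 45.8% of those past the cdHFD test. The 2 cdHFD ZT2 females with advanced clocks did not make this by blurring the rhythm, since without them the counts were 630 and 3399 and the share was 76.3%. A larger spread in cdHFD was argued against by its median residual SD of 0.311 against 0.377, though the larger chow spread could raise fitted chow amplitudes and stays open. Group-wide technical differences among the chow times stay open and could add to the chow count, because the 12 h contrast called 1883 genes in chow, of which 278 were among the 3164, and 196 in cdHFD, where total counts and mitochondrial shares alternated likewise. Without the genes past it, 2886 genes were rhythmic in chow and 402 in cdHFD and the share was 82.2%, and a damping of rhythms by the diet stays open beside that explanation.

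Over 100 splits of the libraries for each count, or 35 at a single time, only the real one (1 split) gave as many genes as the real value for 12 of the 13 results. Chance could be excluded in this way for the diet effects. The splits of time and of sex were made in both diets at once. They exclude chance for rhythm and for sex over both diets together. They cannot do so for 1 diet alone, since the effect broken up in the other diet added to the shared residual spread. For diet by time, the difference in rhythm and sex by diet, the splits also broke up the diet or sex effect itself. That effect then added to the residual spread, so these splits cannot exclude chance for the interactions alone. The real value and the highest of the other splits were 11092 and 4 genes for the averaged diet effect, 1030 and 462 for diet by time, 7446 and 5767 for ZT2, 7149 and 4 for ZT8, 6352 and 2355 for ZT14, and 6972 and 5 for ZT20. They were 3164 and 1222 for rhythm in chow, 441 and 1 for rhythm in cdHFD, 649 and 523 for the difference in rhythm, 1691 and 232 for sex in chow, 168 and 10 for sex in cdHFD, and 331 and 1 for sex by diet. For the share with smaller amplitude, 82.4%, a value as large was given by 4 of 100 splits, the highest at 88.0%. These splits broke up the diet effect too, so they do not settle whether chance gave the share.

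In 6 of 64 tests of a library measure within a group of 4, a library lay apart from the other 3 by more than Dixon's critical value, where chance gives about 1 in 20. These were total counts in chow ZT8 replicate 4 (54.6 M against 40.6, 40.1 and 41.0 M) and in cdHFD ZT14 replicate 4 (36.7 M), and the share of the 10 most abundant genes in cdHFD ZT8 replicate 1 (14.3%). The others were the Alb share (4.502%) and the number of genes with at least 10 counts (17485) in cdHFD ZT20 replicate 3, and the TMM factor of cdHFD ZT2 replicate 3 (1.26).

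Differences between times, diets and sexes were each found by a test of the difference itself, edgeR's quasi-likelihood interaction test with Benjamini-Hochberg adjustment. The diet effect differed between the 4 times for 1030 genes, the rhythm between diets for 649 and the sex difference between diets for 331. The test of rhythm does not separate amplitude from timing. Of the named genes, the diet effect differed between times for Thrsp (adjusted p = 8.92e-04 in edgeR), Cdkn1a (0.00299), Dbp (0.00334), Abcc12 (0.00355), Slc51b (0.00378), Upp2 (0.009002), Atf3 (0.0187), Chrna4 (0.0251), Hnf4aos (0.0344), Ube2c (0.0387), Cdc20 (0.0458), Fgf21 (0.0473) and Mup12 (0.0477). The ZT8 value of Mup12 was -9.01, and -12 without cdHFD ZT8 replicate 2. Genes with a smaller amplitude in cdHFD had adjusted p (edgeR) of 1.96e-04 (Grk5), 5.79e-04 (Tubb2b), 7.62e-04 (Tubb2a), 9.97e-04 (Ppard), 0.00435 (Hspb1), 0.00462 (Paxx), 0.00512 (Cdkn1a), 0.0182 (Col20a1), 0.0304 (Atp2b2) and 0.0391 (Clic3). Those with a larger amplitude had 5.57e-04 (Thrsp), 0.00926 (E2f1), 0.0101 (Mcm6), 0.011 (Uhrf1), 0.0153 (Plk1), 0.0181 (Cdc20), 0.0353 (Slfn9), 0.0447 (Ckap2), 0.0457 (Pole) and 0.0491 (Iqgap3) in edgeR. Those with the largest shifts in peak had 5.34e-04 (Wnt5b), 7.62e-04 (Cenpa and Dtymk), 0.00171 (Fkbp4) and 0.00632 (Mospd1) in edgeR.

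The female minus male log2 difference rose with cdHFD, on the fitted scale, by 5.66 for Cyp4a12a, 5.51 for Cyp4a12b, 5.49 for Mup7, 5.01 for Mup20, 3.51 for Mup21, 3.15 for Nat8f5, 2.98 for Slc22a28 and 2.98 for C4a. It changed by -10.19 for Sult3a1, a value that depends on the prior count, -6.94 for Cyp3a44, -6.46 for A1bg, -6.46 for Cyp3a41b, -6.36 for Cyp2a4, -6.28 for Cyp2b9 and -4.93 for Cyp2b13. The values of Cyp3a44 and Cyp3a41b, at 0.0184 and 0.0179 CPM in chow males, depend on the prior count in part. How reads of the Mup, Cyp and Sult genes were shared among near-identical copies is uncertain.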

How the results depend on the processing

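Every alternative was planned except leaving out cdHFD ZT2 replicates 3 and 4 and total counts for the gene lists, which were chosen after the data were seen. Counts under DESeq2's size factors, total counts alone, limma-voom and no sex term stayed within 1.5 times the main count, as did those not named here under the other settings. Without the filter on low counts the number of genes was 2639 for diet by time, 1108 for rhythm in cdHFD, 1809 for the difference in rhythm, 491 for sex in cdHFD and 798 for sex by diet, and with DESeq2 it was 2146, 754, 1310, 302 and 613. Any difference between the 4 times in place of a 24 h rhythm gave 5732 genes in chow, 970 in cdHFD and 1030 for the difference. Without cdHFD ZT2 replicates 3 and 4 sex by diet gave 211 genes. The cause was not tested for these. Only the smaller number of samples in the last is known by construction.

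With the replicate number as a replicate block, sex in chow gave 96 genes and sex in cdHFD 23, since the number nests sex in all but 1 library and leaves little of it to test. The numbers did not pair the samples, as same-numbered libraries of different groups had correlations of their deviations from the group means between -0.39 and 0.259 (median -0.038, 112 pairs), and 1 of 32 libraries correlated best with its own number. The block changed no other count by over 1.5 times.

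Leaving out each of the 32 libraries in turn gave 10807 to 11374 genes for the averaged diet effect, 6188 to 8207 at ZT2, 6119 to 7459 at ZT8, 5433 to 6630 at ZT14 and 5898 to 7291 at ZT20. It gave 688 to 2065 for diet by time, 2501 to 3896 for rhythm in chow, 279 to 640 in cdHFD, 431 to 1179 for the difference, and 77.8% to 84.7% for the share with smaller amplitude. For sex it gave 1489 to 1828 in chow, 127 to 184 in cdHFD and 267 to 413 for sex by diet. Among named genes the diet call was kept in 27 of these 32 fits for Cyp7a1, 17 for Clec4g, 24 for Eif2s3y and 16 for Kdm5d, and the rhythm difference in 9 for Clic3 and 25 for Atp2b2.

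The log2 value of single genes under averaged diet changed sign as follows, and the cause was not tested beyond the common shift of 0.54 under total counts. With total counts alone it was 0.32 for Nr1d1, 0.39 for Clock, 0.23 for Cry1, 0.26 for Rora, 0.41 for Bhlhe40, 0.48 for Cyp4a14, 0.31 for Apob, 0.13 for Mttp, 0.044 for Tm6sf2, 0.011 for Cyp7a1, 0.30 for Clec4g, 0.016 for Dnase1l3 and 0.46 for Gclc. It was 0.40 for Hspa5, 0.45 for Hspa8, 0.53 for Dnajb1, 0.20 for Atp5b, 0.052 for Ulk1, 0.49 for Xist, 0.48 for Ddx3y, 0.098 for Eif2s3y and 0.22 for Kdm5d. With limma-voom it was -0.14 for Arntl, -0.025 for Npas2 and -1.22 for Cyp2b9, and with the replicate block -0.066 for Npas2, 1.03 for Ddx3y, 0.82 for Eif2s3y and 0.545 for Kdm5d. Without the sex term it was -0.99 for Mup20, -2.43 for Cyp2b9 and 0.064 for Ddx3y, and with DESeq2 0.23 for Sult2a1 and 0.058 for Xist. Of the other values for named genes 317 kept direction and side of the threshold with DESeq2, 323 with its size factors, 308 with limma-voom, 311 without the filter, 257 without the sex term, 314 with the replicate block and 278 with total counts. Of the rest, with their direction kept, 1 gained and 2 lost a call with DESeq2, 3 and 9 with limma-voom, 10 and 2 without the filter, 0 and 2 without the sex term, 0 and 5 with the block and 10 and 13 with total counts. Of 42 lists 15 kept their side of the threshold with an estimated correlation, 27 lost their call, and 42 kept theirs with DESeq2's size factors. Total counts ended 2 of 30 list calls and added 3, and with an estimated correlation they gave 10 calls in place of 3, with 1 in both. Genes under 1 CPM limit the precision, as depth leaves few counts there.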

Other observations

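Of the tests in this part Fisher's exact test of list members was not among those fixed before the data were examined. Adrb3, Cyp51, Srebf2, Plin4, Fitm1, Hsp90aa1, Stip1, Oasl1 and Mx2 were singled out here after their values were seen. Gene lists of cells and tissues other than hepatocytes, macrophages and stellate cells moved in several directions under the diet, averaged over times (log2 ± SE, n = 16 livers per diet). Cholangiocyte markers were higher in 8 and lower in 2 of 13, with the chloride channel gene Cftr, Krt23 and Epcam at 2.23 ± 0.29, 2.07 ± 0.26 and 1.61 ± 0.22, Sox9 at 0.38 ± 0.14 and Krt19 at 0.35 (adjusted p = 0.244 in edgeR's quasi-likelihood test, and 0.59 with adjusted p = 0.0239 without chow ZT14 replicate 2). Sinusoidal endothelial markers were split, 5 higher and 5 lower of 15, with Lyve1 at 1.44 ± 0.23, Cdh5 at 0.66 ± 0.11 and Stab2 at 0.11 (adjusted p = 0.339 in edgeR), while Clec4g (-0.27) and Dnase1l3 (-0.55) turned under total counts, where 13 were higher. Of 14 B and plasma cell markers Bank1 rose (0.87 ± 0.12) and the immunoglobulin joining chain gene Jchain fell (-1.15 ± 0.26), with Cd79a at 0.047 (adjusted p = 0.832 in edgeR). Of 8 erythroid genes 7 fell, among them Hba-a1 (-1.44 ± 0.24), Hbb-bs (-1.25 ± 0.23), Alas2 (-1.27 ± 0.27) and Slc4a1 (-1.61 ± 0.31). Of the white adipose list 4 of 9 genes were measurable, Car3 at -2.66 ± 0.16, Adrb3 at -1.54 ± 0.22 and Cfd (0.83 to 0.0151 CPM) lower and Pck2 at 1.89 ± 0.09 higher, and of the pancreatic acinar list 2 of 13, with Cela1 at -1.11 ± 0.08. Of 9 sex chromosome genes Eif2s3y (-0.45) and Kdm5d (-0.32) were lower, and both turned under total counts. Camera adjusted p over the 42 lists was 0.06 for cholangiocytes, 0.696 for sinusoidal cells, 0.955 for B cells, 0.00542 for erythroid, 0.279 for adipose, 0.144 for acinar and 0.589 for sex chromosome genes. With an estimated correlation these were adjusted p = 0.501, 0.905, 0.981, 0.196, 0.328, 0.30 and 0.747. Under total counts the splits of higher to lower were 13 to 0 for cholangiocytes, 8 to 1 for B cells and 1 to 7 for erythroid genes, and camera called the adipose and acinar lists (adjusted p = 0.00826 and 0.0303, and with an estimated correlation adjusted p = 0.0418 and 0.12), the second on 2 genes. The main counts were the same adjusted over the list alone except that both sex chromosome calls ended.

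Some Kupffer cell, acute phase, cholesterol and lipid droplet genes changed their sex difference with diet. Resident Kupffer cell markers were higher in females in 11 of 14 in chow, while in cdHFD 1 was higher in males, and the change with diet passed for 3, all negative (9 adjusted over the list alone). This was not particular to Kupffer cells. In chow, lipid-associated macrophage markers were higher in females in 10 of 20, T and NK cell markers in 7 of 18 and interferon genes in 10 of 22. In males 1, 1 and 0 were higher, and in cdHFD 0 differed by sex. Of 9 neutrophil markers 0 differed by sex in chow. The acute phase gene Lcn2 was 1.83 higher in chow females than males and -0.33 in cdHFD, a change of -2.16 (adjusted p = 2.88e-05 in edgeR's quasi-likelihood test), and 7 of 24 acute phase genes changed in that direction (9 adjusted over the list alone). Cholesterol synthesis and uptake genes did so in 8 of 25 (16 adjusted over the list alone), among them Sqle (-1.07), Cyp51 (-1.27) and Srebf2 (-0.64), and lipid droplet genes the other way in 4 of 18 (6 adjusted over the list alone), with Plin4 at 1.99 and Fitm1 at 1.85. Camera adjusted p was 4.38e-08 for Kupffer cells, 1.40e-06 for the acute phase, 2.14e-15 for cholesterol and 1.78e-07 for lipid droplets. Of these the lipid droplet shift held with an estimated correlation (adjusted p = 0.0194), and for the others adjusted p = 0.141, 0.111 and 0.111 with an estimated correlation.

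Some heat shock genes differed in rhythm between diets, by a test that does not separate timing from amplitude. Hsp90aa1 had an amplitude of 1.02 with a peak at ZT 18.4 in chow and 0.26 in cdHFD, and Stip1 one of 0.54 at 18.6 and 0.37 at 10.8 (adjusted p of the difference 7.62e-04 and 2.29e-04 in edgeR's quasi-likelihood test). Of 16 heat shock genes 8 differed in rhythm between diets (12 adjusted over the list alone), and of 22 interferon response genes 6 did (9 adjusted over the list alone), with Oasl1 and Mx2 each at adjusted p = 0.00435 in edgeR. By Fisher's exact test both lists held more such genes than all genes tested (adjusted p = 6.10e-07 and 0.00107).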
